A study of Mus musculus with 12 samples.

How the data were processed

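Total RNA was extracted from inguinal subcutaneous fat of single mice, and paired-end libraries were prepared with a TruSeq RNA kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Reads were trimmed with fastp, per the labels' protocols. The submitters' processing notes name HISAT2, DESeq2 1.24.0 and the mouse build GRCm38, without their order or role. The program that made the expression values and its annotation are not given in the sources used here. The strand setting is likewise not given, so overlapping and antisense genes, and genes with near-identical copies, are uncertain.

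The deposited table holds 1 signal value per gene and library, which the authors' file title calls TPM, a transcript abundance scaled by gene length to a fixed total. It has 55416 rows, of which 3798 repeat a gene identifier with identical values. These repeats took the column sums to between 1252773 and 1296301. Each gene was kept once, which left 51618 genes and column sums of 990800 to 994475. TPM is scaled to a fixed total, so the depth of each library is unknown and no interval for counting error is given. A rise of a few abundant genes lowers all others on this scale. The identifiers of 48735 genes were found in GENCODE M21, whose GRCm38 coordinates are used. No pair of libraries held identical values.

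Groups were taken from the labels, with 3 uninjured wild-type, 6 wounded wild-type and 3 wounded knockout libraries. The titles name the mice called wild type here by strain, as c57BL/6, and the others as prdm16-KO. They do not give the strain background of the knockouts or say whether the groups were littermates. Library numbers are those in the titles. The tests, the gene lists and the alternatives were fixed before the data were examined, except those named as added. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 3 group means fitted over all 12 libraries. Genes with a TPM of at least 1 in at least 3 libraries were kept, which left 15318. Two-sided moderated tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. Prdm16 was also tested by exact permutation.

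A total of 28 gene lists with 439 listed genes was fixed, covering adipocyte function, immune and stromal cell types, tissues adjoining the fat pad, and sex-linked genes. Of the listed genes 432 were found, 2 of them through an older symbol, and 7 were not analysed here. The 27 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, and again with an estimated correlation, and with fry. The sex-linked list was not tested. The level of a list in a library is the mean log2(TPM + 1) of its members. Named genes are Prdm16, the 10 largest rises and falls past the threshold with further conditions, of which there were 0 in each comparison, and for each list described the first 2 members as written and up to 4 with the smallest p. Some genes that this rule names are not reported here.

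The alternatives were pseudocounts of 0.1 and 5, other filters, median-of-ratios and quantile scaling, only the groups compared, wounded wild-type numbers 1 to 3 or 4 to 6 only, a robust fit, array weights, a fold threshold, the library number as a term, and leaving out each library. Added after seeing the data were the run of table columns as a term, the epithelium level as a covariate, and leaving out the libraries whose marker lists stood apart. Shared controls were simulated 100 times. The scripts were tested on simulated data with 200 changed genes among 15318. In the injury comparison 58% of changes of 2-fold, 93.5% of 4-fold and 97.5% of 16-fold were recovered, and in the knockout comparison 50.5%, 94% and 98.5%. Between 5 and 14 unchanged genes were called in each run. The changed genes were drawn from the more highly expressed ones. Genes were simulated as independent, with normal noise of the same spread in all groups, and no library stood apart. These rates can therefore overstate what the real libraries allow. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.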

Results

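Inguinal subcutaneous white adipose tissue, the fat pad under the skin of the groin, was profiled by RNA sequencing in 12 mice, 1 library per mouse. The libraries fall into 3 groups. Uninjured wild-type mice gave 3 libraries, wild-type mice 7 days after a skin injury gave 6, and injured mice lacking the transcription factor Prdm16 in adipocytes gave 3. The titles label the wild-type mice c57BL/6 and do not give the strain background of the knockouts, so background and genotype cannot be told apart. The labels did not say which 3 of the 6 wounded wild-type libraries belonged to which of the 2 comparisons of the series, so all 6 served in both, and values against numbers 1 to 3 and against numbers 4 to 6 are given as well for Prdm16 and for each list called. Values are deposited TPM, transcript abundances scaled by gene length to a fixed total, which keep no record of sequencing depth, so the depth behind each value is unknown. With each gene counted once, the libraries summed to between 990800 and 994475 TPM. Between 13573 and 15357 genes reached a TPM of 1 in a library.

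Prdm16 (ENSMUSG00000039410), the targeted gene, lies on chromosome 4 from 154316125 to 154636873 on the minus strand (GRCm38). It stood at 10.01, 10.96 and 11.8 TPM in the uninjured libraries, at 8.02, 5.99, 8.68, 10.7, 10.2 and 11.1 TPM in wounded wild-type libraries 1 to 6, and at 7.29, 5.53 and 5.05 TPM in the wounded knockout libraries. The knockout mean was 5.96 ± 1.18 TPM (SD, n = 3) against 9.11 ± 1.93 TPM (SD, n = 6) in wounded wild-type tissue. The difference was -0.53 with a standard error of 0.19 on the log2(TPM + 1) scale (exact two-sided permutation p = 0.0357, n = 3 and 6, where 0.0119 was the smallest p possible). Across all genes it missed the threshold (limma adjusted p = 0.0971). It was -0.30 against numbers 1 to 3 (exact permutation p = 0.2) and -0.76 against numbers 4 to 6 (exact permutation p = 0.1), and 0.1 is the smallest p that 3 libraries against 3 can give. Knockout and wounded wild-type libraries overlapped, since wounded wild-type library 2 lay below knockout library 1. Transcript remaining in the knockout tissue can come from other cells or from exons outside the deleted part, which TPM per gene does not separate. The fall of Prdm16 was smaller than that of the white adipocyte identity list (mean -0.94) and of Adipoq (-0.82) in the same comparison. Wounded wild-type library 2, the lowest of its group for Prdm16, was also the lowest for the white adipocyte list, at 8.96 on the log2(TPM + 1) scale. Wounded wild-type library 1 went the other way, with a list level of 9.87 against 9.80 and 9.82 in libraries 4 and 6, but less Prdm16. Whether Prdm16 follows adipocyte markers across libraries was not tested, and its fall alone does not show the deletion. After injury Prdm16 differed by -0.26 (exact permutation p = 0.238, n = 6 and 3). With numbers 1 to 3 only it differed by -0.49 (exact permutation p = 0.1, the smallest possible), and with 4 to 6 only by -0.030 (exact permutation p = 0.8).

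**Figure D1:**
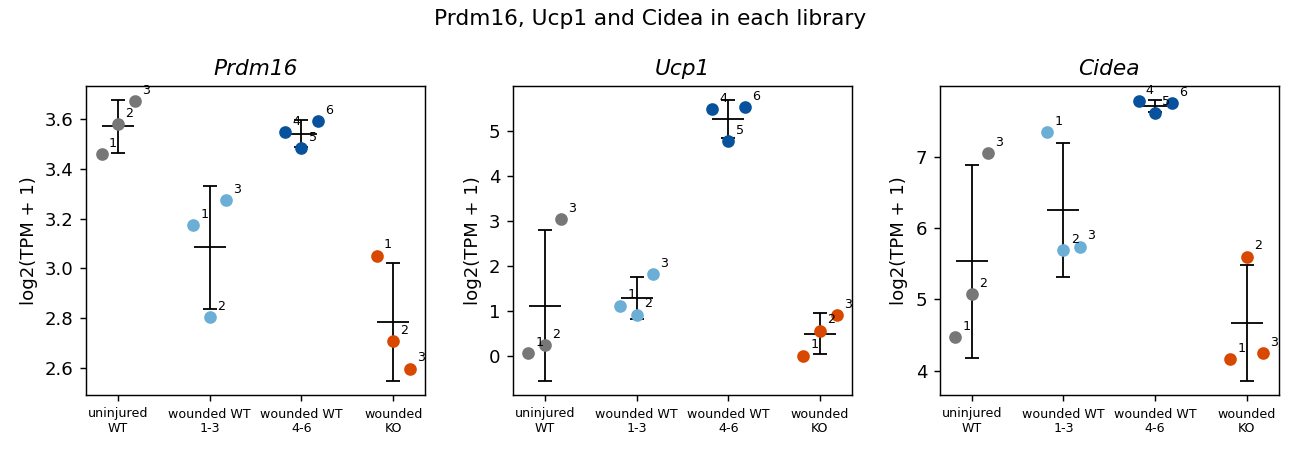
Level of Prdm16, Ucp1 and Cidea in each library as log2(TPM + 1), with numbered points for libraries and a bar with whiskers for the mean and SD of each column. Ucp1 lay between 26.2 and 45.0 TPM in wounded wild-type libraries 4 to 6 and between 0.88 and 2.49 TPM in libraries 1 to 3.

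Several libraries held other tissues in unequal amounts. The skeletal muscle list averaged 7.20 on the log2(TPM + 1) scale in uninjured library 3 and between 0.70 and 1.84 in all other libraries, and Acta1, skeletal muscle actin, stood at 1461 TPM there. The mammary and glandular epithelium list averaged 0.40 in uninjured library 3 and 0.39 in wounded wild-type library 4, against 3.26 to 5.43 in the others. B cell markers averaged 7.31 in knockout library 3 and 4.33 in wounded wild-type library 4, with at most 2.33 elsewhere, and immunoglobulin segments summed to 26173 TPM in knockout library 3. Wounded wild-type library 2 had a macrophage list level of 6.23, inside the knockout range of 5.96 to 6.67.

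**Figure D2:**
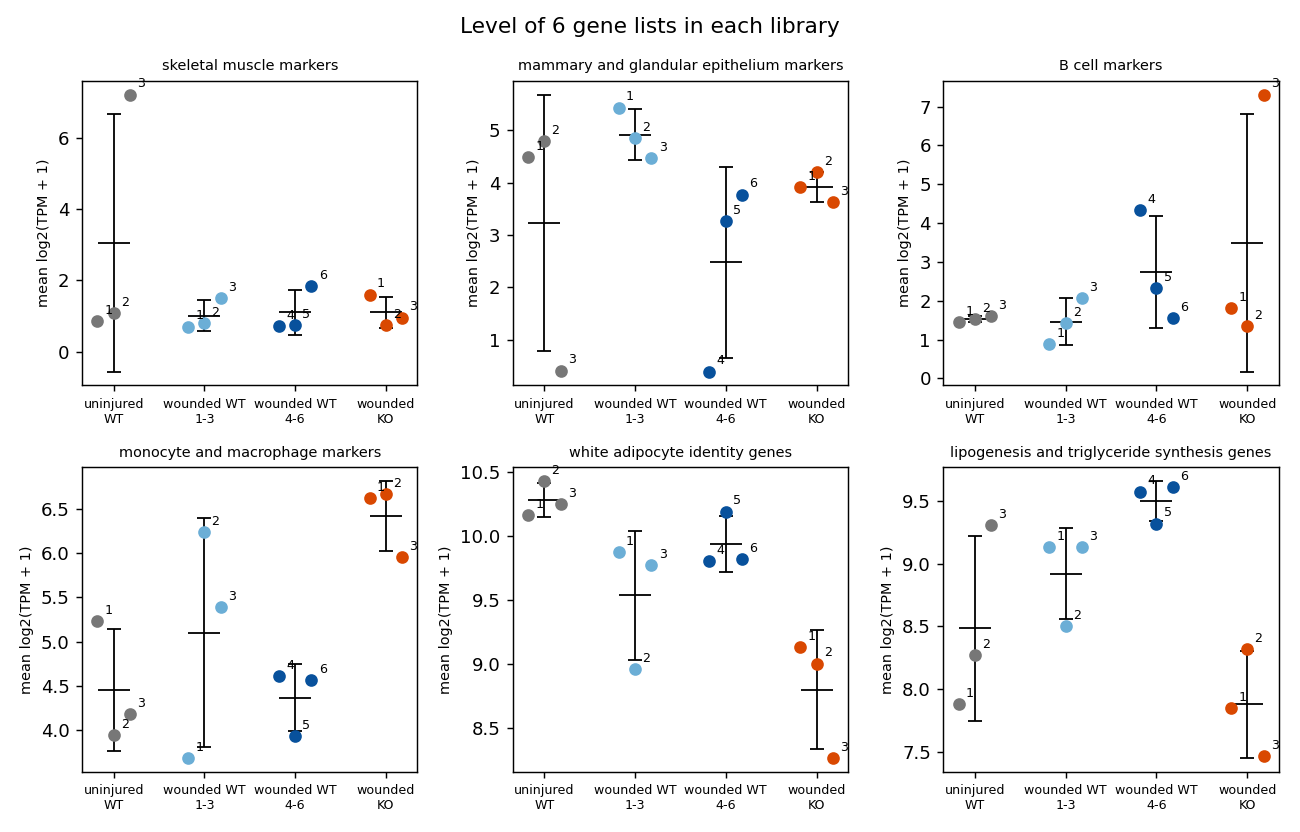
Mean log2(TPM + 1) of 6 gene lists in each library, with numbered points for libraries and a bar with whiskers for the mean and SD of each column. Uninjured library 3 stands at 7.20 for skeletal muscle markers and knockout library 3 at 7.31 for B cell markers.

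The injury comparison asked how fat near a skin wound differed from that of uninjured mice. Lipid synthesis, thermogenic and mitochondrial gene lists rose and the white adipocyte identity and interferon lists fell, by the camera test with its preset correlation, while 0 lists passed with an estimated correlation. The lipogenesis and triglyceride synthesis list had a mean log2 fold change of 0.72 over 19 genes (adjusted p = 3.1e-09), with 15 members higher. Fasn, fatty acid synthase, on chromosome 11 from 120805846 to 120824547, averaged 6902 ± 1919 TPM (SD, n = 6) after injury and 3641 ± 3397 TPM (SD, n = 3) without it. Acly, which makes cytosolic acetyl-CoA from citrate, averaged 1288 ± 606 against 445 ± 470 TPM, and Slc25a1, the mitochondrial citrate carrier, 2028 ± 493 against 913 ± 710 TPM. Acaca, acetyl-CoA carboxylase, had a log2 fold change of 1.20. The thermogenic list had a mean of 0.68 over 22 genes (adjusted p = 4.2e-06), with 19 members higher. Ucp1, the uncoupling protein of brown and beige adipocytes, on chromosome 8 from 83290352 to 83298452, stood at 0.04, 0.18 and 7.23 TPM in uninjured tissue and at 1.16, 0.88, 2.49, 43.7, 26.2 and 45.0 TPM in wounded libraries 1 to 6. Cidea, a lipid droplet protein, had a log2 fold change of 1.45, Cited1 of 2.59 and Elovl3, a fatty acid elongase, of 1.39. Oxidative phosphorylation genes had a mean of 0.30 over 25 genes (adjusted p = 3.1e-09), with Cox5a at 0.48. Glycolysis and hypoxia genes had a mean of 0.38 (adjusted p = 5e-06), with Pfkl at 0.78 and Eno1 at 0.85. Fatty acid oxidation genes had a mean of 0.19 (adjusted p = 0.0017). With an estimated correlation each of these lists had an adjusted p = 0.709. The estimate lay between 0.27 and 0.80 for them, far above the preset of 0.01.

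The rise of these metabolic lists was larger against wounded libraries 4 to 6 than against 1 to 3. The thermogenic mean was 1.08 with 4 to 6 only (adjusted p = 1.3e-17) and 0.27 with 1 to 3 only (adjusted p = 0.276). The lipogenesis mean was 1.01 and 0.43 (adjusted p = 6.5e-16 and 0.0385), the oxidative phosphorylation mean 0.48 and 0.12 (adjusted p = 9.1e-21 and 0.0937), the glycolysis mean 0.54 and 0.23 (adjusted p = 1.3e-09 and 0.0577) and the fatty acid oxidation mean 0.37 and 0.018 (adjusted p = 1.5e-10 and 0.874). These calls rested on the preset correlation, since 0 lists passed in either set with an estimated one. The adjusted p was then 0.107 for thermogenic genes, 0.383 for lipogenesis and oxidative phosphorylation, 0.263 for glycolysis and 0.495 for fatty acid oxidation with 4 to 6 only. Uninjured library 3 had the highest lipogenesis and thermogenic list levels of its group, and without it the means were 1.14 and 0.97. The oxidative phosphorylation mean was then 0.47, the glycolysis mean 0.58 and the fatty acid oxidation mean 0.30. Without uninjured library 1 the lipogenesis mean was 0.42, the oxidative phosphorylation mean 0.15, the glycolysis mean 0.25 and the fatty acid oxidation mean 0.081, which did not pass (adjusted p = 0.389). The fatty acid oxidation mean was 0.32 without wounded library 2.

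The white adipocyte identity list fell after injury, with a mean of -0.55 over 18 genes (adjusted p = 8.7e-05) and 15 members lower. Lep, which encodes leptin, averaged 85.5 ± 38.2 TPM (SD, n = 6) against 320 ± 118 TPM (SD, n = 3), and Plin4, a lipid droplet coat protein, 379 ± 116 against 859 ± 221 TPM. Nnat, neuronatin, averaged 274 ± 196 against 1422 ± 657 TPM. The groups did not overlap for these 3 genes, each with a limma adjusted p = 0.509. The genes were named by a small p in this comparison, Lep also as a first member, so this adds no support. Over all genes 477 were lower without overlap, and 4.17% did not overlap in either direction, where chance gives 2.38%. Adipoq, adiponectin, had a log2 fold change of -0.37. The list's mean was -0.75 with wounded libraries 1 to 3 only (adjusted p = 4.6e-07) and -0.34 with 4 to 6 only (adjusted p = 0.123). Interferon response genes fell with a mean of -0.64 (adjusted p = 5e-06), and 15 of 15 were lower. Gbp2, an interferon-induced GTPase, averaged 41.8 ± 7.15 against 73.3 ± 14.6 TPM, and Ifit3 had a log2 fold change of -1.14. The interferon mean was -0.71 with wounded libraries 1 to 3 only and -0.56 with 4 to 6 only (adjusted p = 5.8e-05 and 0.0013), and -0.25 without uninjured library 1 (adjusted p = 0.0075). With an estimated correlation both lists had an adjusted p = 0.709.

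Lists of inflammation and matrix rose after injury in part. Extracellular matrix and myofibroblast genes had a mean of 0.51 (adjusted p = 0.00019), with Col1a1 at 1.14 and Col3a1, which also encodes a fibrillar collagen, at 0.45. The mean was 0.17 without wounded library 2 and 0.79 without wounded library 1. Neutrophil markers had a mean of 0.92 over 8 genes (adjusted p = 0.0076), with S100a8 at 1.97 and S100a9 at 2.09, both alarmins. The neutrophil mean was 0.38 without wounded library 2 (adjusted p = 0.0622). Cell cycle genes had a mean of 0.44 (adjusted p = 0.001), which became 0.099 without wounded library 2 (adjusted p = 0.109), and Mki67 stood at 0.13 and Top2a at 0.50. Immediate early genes had a mean of 0.26 (adjusted p = 0.0272), or 0.10 without wounded library 2 (adjusted p = 0.241). They also missed the threshold without uninjured library 2 or 3 (adjusted p = 0.0739 and 0.0711). Keratinocyte markers had a mean of 0.68 (adjusted p = 0.0387), with Krt14 at 1.48, and -0.0091 without uninjured library 3 (adjusted p = 0.495). This list also missed the threshold without wounded library 1, 2, 5 or 6 or knockout library 2, and its mean was 1.16 without uninjured library 1 and 1.07 without wounded library 4. The skeletal muscle list fell with a mean of -2.39 (adjusted p = 0.00077), and Acta1 lay between 0.75 and 10.1 TPM after injury and at 34.9, 35.5 and 1461 TPM in the uninjured libraries. Without uninjured library 3 the list's mean was 0.047 (adjusted p = 0.0788), and without uninjured library 1 it was -3.69. With an estimated correlation these 6 lists also had an adjusted p = 0.709.

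Several of these inflammation and matrix rises were larger, or passed, with wounded libraries 1 to 3 only at the preset correlation. That set holds library 2 and is uneven. In libraries 1 to 3 the neutrophil list level was 1.43, 3.98 and 2.13, and the matrix list level 4.62, 7.68 and 6.58. For the matrix list library 1 lay below the uninjured range of 5.15 to 5.86. With 1 to 3 only and 4 to 6 only, the neutrophil mean was 1.66 and 0.18 (adjusted p = 0.0019 and 0.125) and the matrix mean 0.83 and 0.20 (adjusted p = 0.00039 and 0.00065). The keratinocyte mean was 1.42 and -0.053 (adjusted p = 0.0015 and 0.644) and the immediate early mean 0.42 and 0.094 (adjusted p = 0.0178 and 0.15). Cell cycle genes passed with 4 to 6 only, with means of 0.43 and 0.45 (adjusted p = 0.0619 and 2.2e-08). The muscle mean was -2.45 and -2.34 (adjusted p = 0.0051 and 0.0284). None of them passed with an estimated correlation, where the adjusted p was 0.741 for the neutrophil and matrix lists with 1 to 3 only and 0.659 for the matrix list with 4 to 6 only.

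The other 14 lists did not pass after injury. Their mean log2 fold changes were 0.28 for monocytes and macrophages (adjusted p = 0.0525), 0.22 for cytokines and chemokines, 0.59 for B cells, 0.030 for T and NK cells, 0.096 for mast cells and eosinophils, and -0.17 for adipose progenitors. They were -0.14 for secreted repair and growth factors, -0.092 for endothelium, 0.68 for mammary epithelium, 0.18 for nerve and Schwann cells, 0.30 for red blood cells, -0.14 for clock genes, -0.17 for lipolysis and 0.13 for creatine and calcium cycling. The T and NK cell list had a median of -0.027, opposite in sign to its mean. Some of these lists passed when 1 library was left out. The macrophage mean was 0.67 without uninjured library 1 (adjusted p = 0.0017), 0.49 without wounded library 1, 0.44 without wounded library 5 and 0.32 without wounded library 6. The mammary mean was 1.57 and 1.73 without uninjured library 1 or 2 and 1.59 without wounded library 4. Nerve markers passed without uninjured library 3, wounded library 2 or knockout library 1, and B cell markers without knockout library 3 (adjusted p = 0.0208). With wounded libraries 1 to 3 only, macrophage (mean 0.65, adjusted p = 0.0051), mammary (mean 2.35, adjusted p = 1e-04) and red blood cell lists (mean 1.39, adjusted p = 0.001) passed. With 4 to 6 only, B cell (mean 1.29, adjusted p = 0.0057) and nerve lists (mean 0.49, adjusted p = 0.0011) did. All these calls were at the preset correlation, and none held with an estimated one. The adjusted p was then 0.741 for the macrophage, mammary and red blood cell lists, 0.659 for B cells and 0.503 for nerve in these sets.

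No single gene passed in the injury comparison. Of 15318 genes tested with limma, 0 reached an adjusted p under 0.05, the smallest being 0.066, and 970 had an unadjusted p under 0.05, of which 224 were higher and 746 lower. Adjusted over the list alone, 9 lipogenesis and 2 thermogenic genes were higher and 3 white adipocyte genes, 1 interferon gene and 1 muscle gene were lower, against 0 over all genes tested. The first 2 counts moved when wounded libraries 1 to 3 and 4 to 6 were fitted as separate groups. With 4 to 6, 10 lipogenesis and 9 thermogenic genes were higher. With 1 to 3, 0 lipogenesis genes were higher and 1 was lower, and 1 thermogenic gene was higher. Without uninjured library 3 the count was 36, with 10 higher and 26 lower, and without wounded library 5 it was 1. With limma's array weights it was 1493, with 468 higher and 1025 lower. Against numbers 1 to 3 only it was 1, and against numbers 4 to 6 only it was 2.

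**Figure D3:**
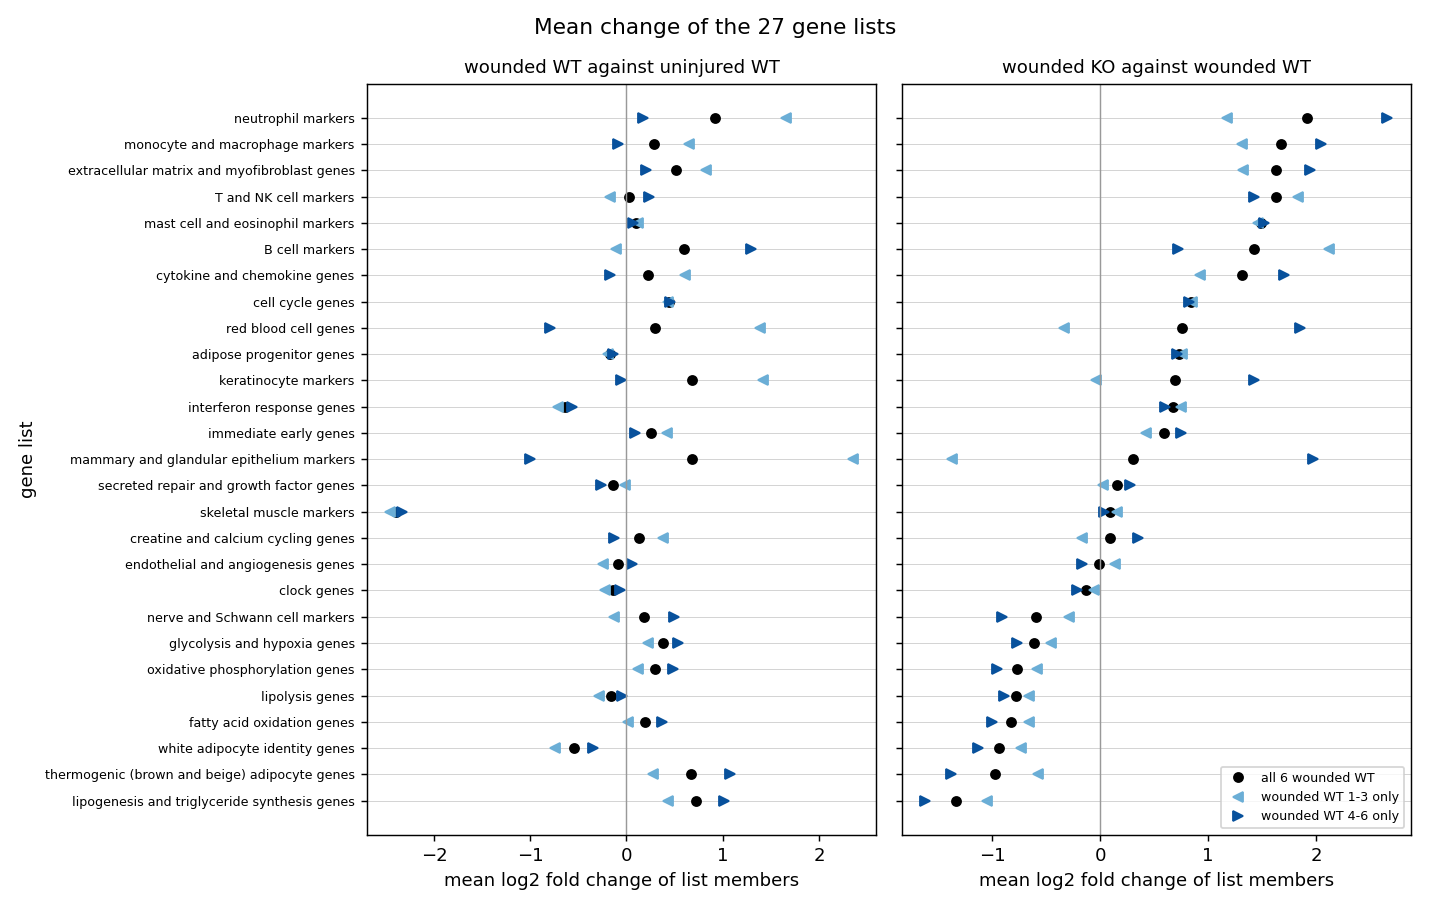
Mean log2 fold change of the members of 27 gene lists after injury (left) and in the knockout (right), with circles for all 6 wounded wild-type libraries and triangles for numbers 1 to 3 or 4 to 6 alone. The lipogenesis list stood at 0.72 after injury and at -1.33 in the knockout.

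The knockout comparison asked how wounded fat without adipocyte Prdm16 differed from wounded wild-type fat, which the series describes as a test of inhibited browning. By the camera test with its preset correlation, lists of lipid synthesis, thermogenesis, mitochondrial oxidation, white adipocyte identity, lipolysis and glycolysis fell and matrix and myeloid lists rose, while 0 lists passed with an estimated correlation. The lipogenesis list fell with a mean of -1.33 over 19 genes (adjusted p = 1.2e-16), and all 19 were lower adjusted over the list alone. Fasn averaged 2457 ± 1390 TPM (SD, n = 3) against 6902 ± 1919 TPM (SD, n = 6), Acaca 187 ± 31.3 against 594 ± 191 TPM, and Dgat1, which completes triglyceride synthesis, 166 ± 52.3 against 342 ± 59.7 TPM. Pnpla3 had a log2 fold change of -1.23. The thermogenic list fell with a mean of -0.98 over 22 genes (adjusted p = 9.8e-09), with 11 lower and 1 higher adjusted over the list alone. Against wounded wild-type libraries 1 to 3, fitted as their own group, 0 were lower and 0 higher in that way. Ucp1 stood at 0.47 and 0.86 TPM in knockout libraries 2 and 3 and was listed at 0 in library 1. Cidea averaged 27.4 ± 17.4 against 148 ± 77.6 TPM, Cox8b, a cytochrome c oxidase subunit, 321 ± 175 against 835 ± 109 TPM, and Adrb3, the β3-adrenergic receptor, 102 ± 39.4 against 228 ± 59.4 TPM. Oxidative phosphorylation genes fell with a mean of -0.77 (adjusted p = 7.1e-20), 24 of 25 adjusted over the list alone, and Ndufb8 had a log2 fold change of -1.01. Mitochondrially encoded genes held 6.96, 6.01 and 7.21% of TPM in the knockout libraries and 7.11 and 7.71% in wounded wild-type libraries 2 and 3, against 10.4 to 11.6% in libraries 1 and 4 to 6, so this share was low in some wild-type libraries too. Fatty acid oxidation genes fell with a mean of -0.83 (adjusted p = 6.9e-15), 18 of 19 adjusted over the list alone and 1 higher, with Cpt2 at -1.08 and Acadm at -0.91. These 4 lists had an adjusted p = 0.182 with an estimated correlation, and by fry, which tests the members of a list alone, an adjusted p = 0.0236.

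The white adipocyte identity list fell in the knockout with a mean of -0.94 (adjusted p = 1.2e-13), 14 of 18 adjusted over the list alone. Trarg1, a protein of glucose transporter vesicles, averaged 53.0 ± 14.6 TPM (SD, n = 3) against 132 ± 38.0 TPM (SD, n = 6), and Slc2a4, the insulin-responsive glucose transporter, 85.3 ± 33.2 against 193 ± 42.2 TPM. Adipoq had a log2 fold change of -0.82 and Lep of -0.77. Lipolysis genes fell with a mean of -0.78 (adjusted p = 1.4e-08), 9 of 14 adjusted over the list alone. Lipe, hormone-sensitive lipase, had a log2 fold change of -1.21. Pnpla2, adipose triglyceride lipase, averaged 971 ± 362 against 2024 ± 611 TPM, and Hcar1, a lactate receptor, 30.6 ± 8.80 against 80.9 ± 19.5 TPM. Glycolysis and hypoxia genes fell with a mean of -0.61 (adjusted p = 5.3e-07), 8 of 14 adjusted over the list alone and 1 higher, and Ldha stood at -0.89. These 3 lists also had an adjusted p = 0.182 with an estimated correlation, and by fry an adjusted p = 0.0236. Nerve and Schwann cell markers fell with a mean of -0.60 (adjusted p = 0.0019, and adjusted p = 0.412 with an estimated correlation). The nerve list's mean was -0.96 without knockout library 1 and -0.36 without knockout library 2 (adjusted p = 0.0473), and -0.29 with wounded wild-type libraries 1 to 3 only (adjusted p = 0.0667) and -0.91 with 4 to 6 only (adjusted p = 0.00011).

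With the preset correlation the adipocyte lists fell against both sets of wounded wild-type libraries. With 1 to 3 only and 4 to 6 only, the mean was -1.04 and -1.62 for lipogenesis, -0.57 and -1.38 for thermogenic genes, -0.59 and -0.95 for oxidative phosphorylation, -0.66 and -1.01 for fatty acid oxidation, -0.74 and -1.14 for white adipocyte identity, and -0.66 and -0.89 for lipolysis. The adjusted p was 7.7e-06 or smaller in each of these 12 tests. Fewer members were lower adjusted over the list alone against 1 to 3, fitted as their own group. The counts were 9 for lipogenesis, 0 for thermogenic genes, 18 for oxidative phosphorylation and 12 for fatty acid oxidation. They were 6 for white adipocyte identity and 7 for lipolysis. It was 0.343 with 1 to 3 only and 0.185 with 4 to 6 only under an estimated correlation. The glycolysis mean was -0.45 and -0.77 (adjusted p = 4e-05 and 7.3e-07), and 0.343 and 0.185 were its adjusted p under an estimated correlation too. Against 1 to 3 as their own group, 1 glycolysis gene was lower and 1 higher adjusted over the list alone.

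Matrix and myeloid lists rose in the knockout. Extracellular matrix and myofibroblast genes had a mean of 1.63 over 27 genes (adjusted p = 1.6e-05), 17 adjusted over the list alone. Against wounded wild-type libraries 1 to 3, fitted as their own group, this count was 1. Postn, periostin, on chromosome 3 from 54361109 to 54391037, had a log2 fold change of 1.57. Col3a1 averaged 4487 ± 1792 TPM (SD, n = 3) against 1620 ± 717 TPM (SD, n = 6), and Col1a1 2065 ± 995 against 690 ± 626 TPM. Mmp13, a collagenase, averaged 10.6 ± 0.93 against 1.78 ± 3.60 TPM. Monocyte and macrophage markers had a mean of 1.68 over 22 genes (adjusted p = 1e-04), 13 adjusted over the list alone. The count of macrophage markers was 0 against wounded wild-type libraries 1 to 3 as their own group. Ccr2, the chemokine receptor of inflammatory monocytes, averaged 24.3 ± 0.29 against 6.73 ± 4.41 TPM, Cd68 224 ± 86.4 against 74.0 ± 63.0 TPM, and Adgre1 and Itgax had log2 fold changes of 1.75 and 1.29. Neutrophil markers had a mean of 1.92 (adjusted p = 0.0302), with Retnlg at 3.45 and S100a8 at 2.42, 1.18 against wounded wild-type libraries 1 to 3 only (adjusted p = 0.12) and 1.60 without knockout library 2 (adjusted p = 0.302). Cytokine and chemokine genes had a mean of 1.31 (adjusted p = 0.002), with Cxcl12 at 1.07 and Il1b at 2.26, and 1.22 without knockout library 2 (adjusted p = 0.0718). With an estimated correlation these 4 lists had an adjusted p = 0.496. By fry the macrophage list had an adjusted p = 0.0434, matrix and cytokine lists 0.0451 and neutrophils 0.0625. With wounded wild-type libraries 1 to 3 only and 4 to 6 only, the matrix mean was 1.32 and 1.95, the macrophage mean 1.31 and 2.04, the cytokine mean 0.92 and 1.70, and the neutrophil mean with 4 to 6 only was 2.66 (adjusted p = 0.00028). The adjusted p was 0.0096 or smaller for the first 3 lists in both. The groups overlapped for Col1a1, Cd68, Adgre1, Itgax, S100a8 and Il1b. Wounded wild-type library 2 stood at 37.7 TPM for Il1b and 182 TPM for S100a8, above the knockout maxima of 33.9 and 115 TPM. Postn, Col3a1, Mmp13, Ccr2, Retnlg and Cxcl12 did not overlap, as did 11.5% of all genes. Genes were named in part by a small p in this comparison, so this adds no support.

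Mast cell and eosinophil markers rose with a mean of 1.49 (adjusted p = 0.00094, and adjusted p = 0.362 with an estimated correlation), 8 of 9 adjusted over the list alone. The mean was 1.46 with wounded wild-type libraries 1 to 3 only and 1.52 with 4 to 6 only (adjusted p = 0.00018 and 0.0016). Fcer1a, a chain of the IgE receptor, averaged 8.88 ± 2.06 TPM (SD, n = 3) against 1.46 ± 1.74 TPM (SD, n = 6), and Ccr3 4.33 ± 1.69 against 0.68 ± 0.60 TPM. Cpa3, a mast cell protease, had a log2 fold change of 1.92 and Prg2, an eosinophil granule protein, of 1.52. T and NK cell markers rose with a mean of 1.63 (adjusted p = 0.00099, and adjusted p = 0.496 with an estimated correlation), 7 of 12 adjusted over the list alone, but the mean was 0.57 without knockout library 3 (adjusted p = 0.0298). Cd3e stood at 61.4 TPM in that library and at 1.76 and 3.07 TPM in knockout libraries 1 and 2, and Gzma had a log2 fold change of 0.68. The T and NK cell mean was 1.83 with wounded wild-type libraries 1 to 3 only and 1.43 with 4 to 6 only (adjusted p = 2.7e-05 and 0.067). Against 1 to 3 as their own group, 3 T and NK cell markers were higher adjusted over the list alone. B cell markers had a mean of 1.42 (adjusted p = 0.339), -0.49 without knockout library 3 and 2.25 without knockout library 1, where it passed. Cd3e had a log2 fold change of 1.38, or -0.030 without knockout library 3.

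Smaller changes completed the knockout comparison. Interferon response genes had a mean of 0.67 (adjusted p = 0.0431, and adjusted p = 0.694 with an estimated correlation). Cell cycle genes had a mean of 0.84 (adjusted p = 0.0431, and adjusted p = 0.748 with an estimated correlation). Immediate early genes had a mean of 0.59 (adjusted p = 0.0431, and adjusted p = 0.496 with an estimated correlation). With wounded wild-type libraries 1 to 3 only and 4 to 6 only, the interferon mean was 0.75 and 0.60 (adjusted p = 0.0065 and 0.32), the cell cycle mean 0.85 and 0.83 (adjusted p = 0.0185 and 0.0039) and the immediate early mean 0.42 and 0.75 (adjusted p = 0.0571 and 0.0285). These 3 lists were close to the threshold. The interferon list missed it without wounded wild-type library 1, 2 or 3 or knockout library 1 or 2, with a mean of 0.35 without knockout library 1. The cell cycle list missed it without uninjured library 1 or 3, wounded wild-type library 1, 3, 4 or 5, or knockout library 2 or 3. The immediate early list missed it without uninjured library 1, wounded wild-type library 1, 3 or 4, or knockout library 2. The endothelial list was called lower relative to other genes (adjusted p = 0.0352, and adjusted p = 0.496 with an estimated correlation) with a mean of only -0.015, and its mean was 0.14 against wounded wild-type libraries 1 to 3 only (adjusted p = 0.357) and -0.17 against 4 to 6 only (adjusted p = 0.0019). Without single libraries its mean lay between -0.13 and 0.041, and it missed the threshold without wounded wild-type library 2, 3, 4 or 5 or knockout library 2 or 3. The remaining lists did not pass. Their means were 0.73 for adipose progenitors, 0.69 for keratinocytes, 0.76 for red blood cells, -0.14 for clock genes (adjusted p = 0.0624), 0.15 for secreted factors, 0.095 for muscle, 0.30 for mammary epithelium and 0.090 for creatine and calcium cycling. The test pointed lower for the last 4, opposite in sign to their means, and the creatine list's median was -0.071. Adipose progenitor genes passed without knockout library 3 (mean 0.86, adjusted p = 0.0208), and clock genes without wounded wild-type library 2 or knockout library 1. Mammary epithelium passed against wounded wild-type libraries 1 to 3 only (mean -1.37, adjusted p = 0.0041) and had a mean of 1.98 against 4 to 6 only (adjusted p = 0.475). The same mean of -1.37 came with replicate numbers as blocks (adjusted p = 0.00051) and with the run of table columns as a term (adjusted p = 0.0133). Numbers 4 to 6 occur only in wounded wild-type libraries, and the knockouts share a run with 1 to 3. Both fits therefore compare the knockouts with 1 to 3 and add no separate support. Against 1 to 3 only, B cell markers passed as well (mean 2.12, adjusted p = 0.0217). Against 4 to 6 only, red blood cell (mean 1.85, adjusted p = 0.0456) and clock genes (mean -0.22, adjusted p = 0.0267) passed. None of these held with an estimated correlation, with an adjusted p of 0.584 for mammary epithelium and B cells, 0.573 for red blood cells and 0.247 for clock genes. Within the secreted factor list Fgf7 had a log2 fold change of 1.32 and Nrg4 of -1.29.

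By limma 0 of 15318 genes reached an adjusted p under 0.05 in the knockout, the smallest being 0.0597, while 4851 had an unadjusted p under 0.05, with 3355 higher and 1496 lower. The median log2 fold change of all genes was 0.20. Median-of-ratios rescaling took this median to 0.027 and the split to 2023 higher and 2525 lower, and quantile normalization gave 1772 higher and 2834 lower, so the direction of the majority depended on the scaling. The count rested on single libraries. It was 3169 without wounded wild-type library 2, 2273 without knockout library 2, 1 without wounded wild-type library 3, 2031 against numbers 4 to 6 only and 0 against numbers 1 to 3 only. With limma's array weights it was 2804, with 1881 higher and 923 lower.

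Across genes, the injury and knockout changes had a Pearson correlation of -0.033, where the shared wounded wild-type libraries alone gave -0.33 in simulations with no effect. The covariance was -0.0077 against a simulated -0.043. With the shared libraries split, the correlation was 0.32 for injury with numbers 1 to 3 and knockout with 4 to 6, and 0.035 for injury with 4 to 6 and knockout with 1 to 3. Simulations with no effect, and with no difference between runs of table columns, gave -0.0021 and 0.0011. In the first split both changes compare the knockouts' run of table columns with the uninjured run. A difference between the runs alone would therefore make them correlate. In the second each change stays within 1 run, and 40.5% of genes had the same sign against 50.0% in simulations. The median log2 fold change of all genes was -0.087 for that injury change and 0.14 for that knockout change. Medians of opposite sign can lower the share of equal signs, and the simulations held no such shift. The share therefore does not show that injury and knockout oppose each other. Genes are not independent replicates, and with 0 genes called in either comparison no overlap of called genes could be counted.

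Wounded wild-type libraries 1 to 3 were also compared with 4 to 6, since the 6 can come from 2 experiments. In libraries 1 to 3 the thermogenic list was lower by the camera test (mean -0.81, adjusted p = 3e-09), as was oxidative phosphorylation (mean -0.36, adjusted p = 4.4e-10), while mammary epithelium was higher (mean 3.35, adjusted p = 1.9e-05) and so were red blood cell genes (mean 2.18, adjusted p = 3.8e-06). None of the 19 lists called was called with an estimated correlation. Limma called 3 genes, and 1428 had an unadjusted p under 0.05. Rny3, a small noncoding RNA, averaged 48.8 TPM in libraries 4 to 6, and an unnamed gene averaged 31.9 TPM there, and both were listed at 0 in 1 to 3. The pseudogene Gm15536 averaged 34.3 TPM in 1 to 3 and was listed at 0 in 4 to 6. These 3 genes were named after their values were seen. Rny3 spans only 47781624 to 47781725 on chromosome 6, and Gm15536 only 7038661 to 7038774 on chromosome 10. TPM is scaled by gene length and depth is unknown, so the number of reads behind these values cannot be told. In the table the uninjured libraries stand in 1 run of columns with wounded wild-type 4 to 6, and the knockout libraries in another with 1 to 3. All 3 genes averaged 0 TPM in the uninjured and in the knockout libraries, so they do not follow these runs.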

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

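The tests of explanations in this part were all chosen after the results were seen. The spread of the 6 wounded wild-type libraries was examined for 83 lists and genes, and in 23 the gap between 1 library and the nearest other, as a share of the whole range, was above Dixon's 95% critical value, which chance exceeds in about 1 of 20. Wounded wild-type library 2 stood apart in 18 of them. It was lowest for the white adipocyte identity list (0.661 of the range), the lipolysis list (0.736), the clock list (0.733), Acadm (0.652), Adipoq (0.704), Adrb3 (0.702), Cpt2 (0.786), Lipe (0.72), Pnpla2 (0.785), Pnpla3 (0.644) and Slc2a4 (0.64). It was highest for the neutrophil list (0.71), the immediate early list (0.741), Il1b (0.734), Itgax (0.774), Mmp13 (0.668), S100a8 (0.715) and S100a9 (0.854). Wounded wild-type library 1 was lowest for the endothelial list (0.657), Col3a1 (0.728), Ifit3 (0.673) and Postn (0.663), and library 3 highest for Fcer1a (0.726). Genes of one list move together, so these are not 23 separate events. No explanation of library 2 was tested.

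Other splits of the same libraries were counted for each comparison. After injury 13 of the 84 splits of 9 libraries gave at least the 970 genes at an unadjusted p under 0.05 of the real one, and the highest other gave 2459, so chance cannot be excluded. The split of uninjured library 3 with wounded wild-type libraries 4 and 5 called 237 genes where the real one called 0. It is the highest count of the other splits, and that maximum was not tested against chance. In the knockout 1 of 84 splits, the real one, gave 4851 genes, and the highest other gave 4605, with wounded wild-type library 2 placed among the knockouts. This share has meaning only if all 9 libraries can be exchanged freely. The splits mix wounded wild-type libraries 1 to 3 and 4 to 6, which can be 2 experiments, so they cannot decide whether chance is excluded. Against 1 to 3 only, in the same run of table columns, the count was 1956, and 3 libraries against 3 make too few splits for a share under 0.05. With the run as a term, which also compares the knockouts with 1 to 3 only, the count was 2951. By genes past the adjusted threshold the real grouping was not extreme. The split of wounded wild-type library 2 with knockout libraries 2 and 3 called 1765 genes against 0. It differs from the real grouping only by the exchange of knockout library 1 for wounded wild-type library 2. Between wounded wild-type libraries 1 to 3 and 4 to 6, the real split gave 1428 genes and the highest other 831, and 1 of 10 splits is too few for a share under 0.05.

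The thermogenic list was lower in wounded wild-type libraries 1 to 3 than in 4 to 6. None of the explanations tested is excluded. A part of the fat pad with less glandular epithelium in 4 to 6 stays open, since the epithelium list reached 3.77 there, below the 4.46 of the lowest of 1 to 3, and no libraries of the 2 sets were matched for epithelium. Fewer adipocytes in 1 to 3 stays open too. Subtracting the white adipocyte list level left 0.298 of a difference of 0.698, with an SD of 0.302 and an exact permutation p of 0.2, where 0.1 is the smallest possible. A difference between the runs of table columns cannot be told apart either. The uninjured libraries, in the run of 4 to 6, reached 3.39 against 3.73 for the lowest of those, but injury and the run are mixed there. A difference between 2 experiments with wounded mice stays open as untested.

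In the knockout the adipocyte lists were lower and the macrophage list higher. Lymph node tissue in knockout library 3 is argued against for this pattern. Without that library 7 of 7 lists lay beyond the SD of wounded wild-type libraries and kept their call at the preset correlation, with 0.714 to 1.14 of their mean, though 0 were called with an estimated correlation with it or without it. Whether a lower share of adipocytes that raises all other cell types alike is the whole cause could not be decided. The form of this test was changed after an earlier form had left the question undecided, and chance is not excluded within 1 to 3. Of 15 pairs among 6 lists of other cell types, 4 moved apart by more than their SD and without overlap, against all wounded wild-type libraries and against each set of 3. The nerve list minus the mast cell list lay between -0.56 and -0.15 in the knockouts and between 0.42 and 2.27 in wounded wild-type libraries, and the endothelial list minus the mast cell list between 0.47 and 1.04 against 1.25 to 2.52. As many pairs came in a share of 0.0357 of 84 splits, which mix wounded wild-type libraries 1 to 3 and 4 to 6. Within 1 to 3 only the share was 0.2, so chance is not excluded there, and within 4 to 6 only it was 0.1, the smallest possible. The B cell and T and NK cell lists were left out of that test as lymph node markers. A larger number of macrophages, neutrophils or mast cells, beside a loss of adipocytes, stays open. For the B cell list the mean went from 1.42 to -0.49 without knockout library 3 (adjusted p = 0.0588), and for T and NK cells from 1.63 to 0.57 (adjusted p = 0.0298), so lymph node tissue may account for most of both. Genotype stays open, and it shares a run of table columns with wounded wild-type libraries 1 to 3, against which these falls also passed with the preset correlation.

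The lipogenesis list was higher in uninjured library 3 than in libraries 1 and 2. Skeletal muscle in that library stays open, as 0 other libraries had at least 0.5 of its muscle list level, and its effect on these genes could not be tested. A wrong label also stays open, with values on both sides. On 100 genes chosen without it, its median position was 0.067 between wounded wild-type (0) and the other uninjured libraries (1), while uninjured libraries 1 and 2 lay at 1.10 and 0.639 and wounded wild-type libraries between -0.148 and 0.453 when held out in the same way. The margin between 0.453 and 0.639 is narrow, and the same would be seen if uninjured libraries 1 and 2 shared a feature that has nothing to do with injury. Other values go with the label as given. The white adipocyte list stood at 10.25 in uninjured library 3 and at most at 10.19 in wounded wild-type libraries, though this margin is within their SD of 0.41. Lep, Plin4, Nnat, Gbp2 and Ifit3 lay on the uninjured side in it, with Lep at 194 TPM against at most 158 TPM after injury, but these genes were named by a small p that used this label, Lep also as a first member of its list. The label was kept.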

How the results depend on the processing

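The run of table columns as a term, the epithelium level as a covariate and the 3 settings that leave out named libraries together were chosen after seeing the data, and the other settings were fixed before the data were examined. The depth behind each value is unknown, so its effect on these results could not be measured. The cause of the changes below was not tested, except that settings with fewer libraries also have fewer replicates.

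The number of genes past the threshold was 0 in both comparisons and moved with the setting. After injury limma gave 1 gene with a pseudocount of 0.1, 1 against wounded wild-type numbers 1 to 3 only, 2 against numbers 4 to 6 only, and 1493 with array weights. It gave 2 with the run of table columns as a term and 16 without uninjured 3, knockout 3 and wounded wild-type 4 together. It gave 1 against numbers 1 to 3 without knockout 3 and 130 against numbers 4 to 6 without uninjured 3, with 54 higher and 76 lower. Leaving out single libraries gave between 0 and 36, the highest without uninjured library 3. In the knockout it gave 21 without the filter on low TPM, 2031 against numbers 4 to 6 only, 2804 with array weights, 1 with the run of table columns as a term and 2360 against numbers 4 to 6 without uninjured 3. Leaving out single libraries gave between 0 and 3169, the highest without wounded wild-type library 2. Between wounded wild-type libraries 1 to 3 and 4 to 6 the 3 genes became at most 6, without library 1.

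The list results moved with the test. With an estimated correlation 0 lists passed in either comparison, against 13 and 18. The preset was 0.01, while the estimates with all libraries ran from 0.090 for secreted factors to 0.99 for red blood cells. They were 0.80 for oxidative phosphorylation, 0.68 for lipogenesis, 0.71 for white adipocyte identity and 0.27 for thermogenic genes. The preset treats the members of a list as nearly independent, so its small p-values can overstate the evidence. In 1 alternative, wounded wild-type libraries 4 to 6 only and without uninjured library 3, the thermogenic list passed with an estimated correlation in both comparisons (adjusted p = 0.0154 and 0.038), and in every other alternative 0 lists did. By fry, which tests the members of a list alone and not against other genes, 0 passed after injury and 13 in the knockout. The correlation of the 2 changes was -0.033 with all libraries and 0.32 and 0.035 with the wounded wild-type libraries split both ways. The 0.32 came from the split in which both changes cross the runs of table columns.

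Prdm16 in the knockout passed against numbers 4 to 6 only, at -0.76 with or without uninjured 3, and with array weights, at -0.55. Leaving out single libraries gave -0.66 to -0.43, and it passed without wounded wild-type library 2. It stayed negative under each setting tried. After injury it turned to 0.021 against numbers 4 to 6 without uninjured 3.

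The replicate numbers in the titles shared no more than a number. Libraries with the same number in the uninjured and wounded wild-type groups deviated with correlations of -0.098, 0.11 and -0.16, and in the knockout and wounded wild-type groups of 0.11, 0.24 and 0.023, and not every library correlated best with its own number. With the replicate block limma gave 0 genes in both comparisons, with 1004 and 1590 at an unadjusted p under 0.05, and camera 15 and 16 lists.

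Of 26 named genes after injury, 3 reversed under some setting, and of 40 in the knockout, 1. Of 27 lists, 15 and 9 did, counting a turn of the test's direction or of the mean's sign. In 653 of 837 list values after injury and 678 of 837 in the knockout, direction and side of the threshold were as before. 71 and 80 no longer passed and 37 and 15 newly passed. Genes newly passed 23 times after injury and 158 times in the knockout. The reversed values follow, as log2 fold changes of genes and means of lists. Some settings repeat 1 contrast by design. The replicate block gives the values of numbers 1 to 3 only. The run of table columns as a term gives those of 4 to 6 only after injury and of 1 to 3 only in the knockout. With a pseudocount of 0.1 the test alone turned for T and NK cells at 0.012 after injury. Without the filter on low TPM the value was -0.018 for creatine cycling after injury, and 0.013 for endothelium in the knockout. Only the direction of the test changed for T and NK cells at 0.026 after injury. With a mean TPM of at least 5 the value was -0.14 for secreted factors in the knockout. Under median-of-ratios rescaling the value was -0.098 for creatine cycling, -0.015 for secreted factors and -0.011 for muscle in the knockout. Only the direction of the test changed for T and NK cells at 0.082 after injury, and mammary epithelium at 0.11 in the knockout. Under quantile normalization the value was -0.15 for creatine cycling, -0.098 for secreted factors and -0.17 for muscle in the knockout. There the test, but not the mean, turned for T and NK cells at 0.075 after injury, and mammary epithelium at 0.12 in the knockout. Against wounded wild-type numbers 1 to 3 only the value was -0.040 for Mki67, -0.17 for T and NK cells, -0.11 for B cells and -0.13 for nerve after injury, and -0.17 for creatine cycling, 0.14 for endothelium, -0.043 for keratinocytes, -1.37 for mammary epithelium and -0.33 for red blood cells in the knockout. With the replicate block the value was -0.040 for Mki67, -0.17 for T and NK cells, -0.11 for B cells and -0.13 for nerve after injury, and -0.17 for creatine cycling, 0.14 for endothelium, -0.043 for keratinocytes, -1.37 for mammary epithelium and -0.33 for red blood cells in the knockout. With array weights the value was -0.041 for Krt14, -0.11 for creatine cycling, 0.11 for progenitors, -0.0069 for cytokines, 0.079 for endothelium, -1.60 for mammary epithelium and -0.55 for red blood cells after injury. Only the direction of the test changed for lipolysis at -0.13 and clock genes at -0.024 after injury, and creatine cycling at 0.46, secreted factors at 0.28 and B cells at 0.074 in the knockout. Against wounded wild-type numbers 4 to 6 only the value was -0.16 for Krt14, -0.13 for creatine cycling, -0.17 for cytokines, -0.085 for macrophages, 0.060 for endothelium, -0.053 for keratinocytes, -0.997 for mammary epithelium and -0.79 for red blood cells after injury. There the test, but not the mean, turned for lipolysis at -0.049 and clock genes at -0.063 after injury, and creatine cycling at 0.35, secreted factors at 0.28, B cells at 0.72 and mammary epithelium at 1.98 in the knockout. With the run of table columns as a term the value was -0.16 for Krt14, -0.13 for creatine cycling, -0.17 for cytokines, -0.085 for macrophages, 0.060 for endothelium, -0.053 for keratinocytes, -0.997 for mammary epithelium and -0.79 for red blood cells after injury, and -0.17 for creatine cycling, 0.14 for endothelium, -0.043 for keratinocytes, -1.37 for mammary epithelium and -0.33 for red blood cells in the knockout. The test alone turned there for lipolysis at -0.049 and clock genes at -0.063 after injury. Without uninjured 3, knockout 3 and wounded wild-type 4 together the value was -0.00013 for creatine cycling, -0.31 for T and NK cells, 0.12 for muscle and -0.35 for mammary epithelium after injury, and -0.0076 for B cells, 0.066 for endothelium and -0.38 for mammary epithelium in the knockout. Only the direction of the test changed for lipolysis at -0.16 and endothelium at -0.12 after injury, and creatine cycling at 0.25 and secreted factors at 0.19 in the knockout. With the epithelium level as a covariate the test alone turned for endothelium at -0.061 after injury. Against numbers 1 to 3 without knockout 3 the value was -0.040 for Mki67, -0.17 for T and NK cells, -0.11 for B cells and -0.13 for nerve after injury, and 0.17 for endothelium, -1.14 for mammary epithelium and 0.040 for clock genes in the knockout. Only the direction of the test changed for creatine cycling at 0.070, secreted factors at 0.12 and B cells at 0.21 in the knockout. Against numbers 4 to 6 without uninjured 3 the value was 0.021 for Prdm16, -1.54 for Krt14, -0.33 for creatine cycling, -0.32 for cytokines, -0.22 for macrophages, 0.075 for endothelium, -0.74 for keratinocytes, 0.10 for muscle, -2.94 for mammary epithelium and -0.83 for red blood cells after injury. There the test, but not the mean, turned for lipolysis at -0.035 and clock genes at -0.048 after injury, and creatine cycling at 0.35, secreted factors at 0.28, B cells at 0.72 and mammary epithelium at 1.98 in the knockout. By fry the test alone turned for T and NK cells at 0.030 after injury, and creatine cycling at 0.090, secreted factors at 0.15 and mammary epithelium at 0.30 in the knockout.

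Leaving out single libraries turned further results, with a range after injury of -0.12 to 0.34 for Mki67, -0.077 to 0.26 for creatine cycling, -0.22 to -0.035 for lipolysis, -0.34 to 0.10 for progenitors, -0.11 to 0.42 for cytokines, -0.017 to 0.67 for macrophages, -0.15 to 0.17 for T and NK cells, -0.12 to 0.28 for mast cells, -0.15 to 0.022 for endothelium, -0.0091 to 1.16 for keratinocytes, -3.69 to 0.047 for muscle, -1.26 to 1.73 for mammary epithelium and -0.047 to 0.57 for red blood cells. In the knockout the range was -0.030 to 2.22 for Cd3e, -0.13 to 0.33 for creatine cycling, 0.099 to 0.25 for secreted factors, -0.49 to 2.52 for B cells, -0.13 to 0.041 for endothelium, 0.19 to 1.08 for keratinocytes, -0.23 to 0.31 for muscle, -0.61 to 0.77 for mammary epithelium and -0.13 to 1.30 for red blood cells. The cause was not tested.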

Other observations

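Of 15318 genes, 162 were higher and 477 lower after injury with no overlap between the groups, or 4.17%, where chance gives 2.38% for 3 libraries against 6. In the knockout 1133 were higher and 626 lower, or 11.5%. Libraries within a group had correlations of log2(TPM + 1) of 0.933 to 0.959 for uninjured, 0.904 to 0.977 for wounded wild-type and 0.887 to 0.949 for knockout tissue. The first 3 principal components held 36.1, 16.6 and 12.3% of the variance. Red blood cell genes averaged between 6.81 and 7.68 in wounded wild-type libraries 1 to 3, between 5.43 and 5.87 in libraries 4 to 6, and up to 8.28 in knockout tissue.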
